A study of Mus musculus with 12 samples.

How the data were processed

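ATAC-seq was done on 12 libraries of sorted mouse myeloid cells, 2 in each of 6 groups named by the sample titles. Per the labels, liver cells were obtained by perfusion and digestion in the presence of flavopiridol, separated on density gradients and sorted by flow cytometry. The submitters' processing notes name Bowtie2, HOMER and DESeq2, without versions or roles, and the genome builds mm10 and GRCm38. The depth per library, the read filters and any shift of reads for the transposase are not given in the sources used here.

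The authors deposited 1 peak list per group, named for the irreproducible discovery rate (IDR) per the labels, which compares peaks between replicates; each list belongs to both libraries of its group. Each row of a deposited list holds a position, a signal value and a score, with no header. The signal is the authors' normalized tag count of the peak, and the score is a whole number that the authors' pipeline gave each peak. Both are the authors' own values; they were used to rank and filter peaks within a list and to describe each list by its mean, not to compare the heights of single peaks between lists. In each list, 100% of the signal values below 40 were whole multiples of 1 step (tolerance 0.06), from 0.307 in KC-H to 0.612 in Ly6CLo-RM. The lowest peaks held 27 to 37 such steps. If HOMER's default scaling was used, which no source here states, a smaller step means more tags in total. With lists made from both libraries, there is no value per library, so replicates could not be compared and no test between groups was possible.

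Nearly all peaks were 200 bp wide; 4, 2, 1, 1 and 2 peaks of KC-H, KC-N, KN-RM, Ly6CHi-RM and Ly6CLo-RM were not. Coordinates are those of the lists, and no peak was removed here for lying in repeated or hard-to-map sequence. Gene positions came from a RefSeq table of GRCm38.p6, the build of the lists, with 21883 protein-coding genes. That table has gene starts and ends but no strand, exons or introns. The design fixed before the data were examined named transcription start sites; here both ends of a gene took their place, so a share near gene ends counts 3' ends too. A peak was assigned to the gene that contains its centre, the one with the nearer end if several do, and otherwise to the nearest gene within 100 kb. Position within exons, introns and untranslated regions, and the planned search for motifs, were left out because no genome sequence or exon annotation was used here.

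A list-specific region is a peak in the best-scored 50% of one list that no peak of the whole other list overlaps by 1 bp or more, with ties in score ordered by tag count. Its share of the high-scoring peaks has a 95% Wilson interval, which covers counting error only. Overlap between lists was the number of overlapping peaks of both lists over all peaks of both, for lists as deposited, for equal-length lists of the 34293 best-scored peaks, and for the 22691 best-scored peaks over 1 kb from gene ends. The chance level came from 20 circular shifts within chromosomes. The share of regions found in a further list was set beside that of peaks shared by both lists, matched in 10 score classes. Merged regions were counted by the lists that hold them.

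For 24 gene lists written before the data were examined, the list-specific regions of one direction minus the other were summed over the genes. The sum was placed among 10000 random lists of the same size, matched on the number of peaks per gene; a percentile below 2.5 or above 97.5 is called outside the matched range. The lists cover macrophage states, signalling and metabolic pathways, other cell types and housekeeping genes; 1 listed symbol, of the interferon list, was not in the gene table. Genes are named by a rule fixed beforehand: the 10 with the most list-specific regions per direction, up to 4 members of each gene list with the largest difference, 12 marker genes whatever their values, and the 3 regions of highest score per direction. The text gives a part of these and of the gene lists, and results of 1 gene are not reported here.

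Alternatives chosen before the data were examined were an overlap of 50% of the shorter peak, centres within 200 bp, equal-length lists, the better-scored 50% of every list, all peaks or the best 25% in place of the best 50%, gene windows of 20 and 1000 kb, gene end distances of 500 and 2500 bp, and autosomes and X only. Those added afterwards were ranking by tag count, assignment to the nearest gene end, and absence taken as no peak centre of the other list within 1000 bp, called "by distance". Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

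The functions were tested on simulated lists of the sizes of KC-H and KC-N over 21883 genes. All 42968 planted shared sites and the planted list-specific regions, 1587 and 1263, were recovered. Sites were spaced so that shared ones always overlapped and others never did, so this recovery checks the code only. It does not cover peaks of 2 lists that lie side by side without overlap. All 20 planted gene lists of 20 genes with 8 extra regions were above the 97.5 percentile, and 4.6% of 500 lists without planted regions were outside the range. That share holds for random genes and randomly placed sites, not for clustered peaks at chosen genes.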

Results

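Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in myeloid cells sorted from C57BL/6J mice. The 12 libraries fell into 6 groups of 2, and each group had 1 deposited peak list. Tim4-positive F4/80-high Kupffer cells, the resident macrophages of the liver, came from mice on a control diet (KC-H) and on a diet that models nonalcoholic steatohepatitis, the NASH diet (KC-N). The other 4 groups were from NASH-diet mice: Tim4-negative F4/80-high Kupffer cells (KN-RM), CD11b-high recruited liver macrophages with high Ly6C (Ly6CHi-RM) or low Ly6C (Ly6CLo-RM), and Ly6C-high blood monocytes (Blood-Ly6CHi-NASH). The title KN-RM carries the same RM suffix as both recruited macrophage groups, so the name Kupffer cell does not settle the origin of these cells. The blood list was the longest, with 69616 peaks over 13.9 Mb, followed by KC-H with 63501, Ly6CHi-RM with 61492, Ly6CLo-RM with 54621 and KC-N with 50550. The KN-RM list was the shortest, with 34293 peaks over 6.86 Mb.

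The mean normalized tag count per peak was 94.2 in the blood list, 89.8 in Ly6CHi-RM and 83.4 in Ly6CLo-RM. It was 28.3 in KC-H, 38.5 in KC-N and 27.2 in KN-RM, so the 3 F4/80-high lists had lower means, in the authors' scaling, than the blood and CD11b-high lists. Peaks within 1 kb of an end of a protein-coding gene made up 24.0% of the blood list and 33.8% of the KN-RM list (95% Wilson intervals 23.7% to 24.3% and 33.3% to 34.3%). Of 30873 regions held by all 5 other lists, KN-RM held 81.6% (81.2% to 82.0%). The corresponding share was 96.3% for blood, 96.6% for KC-H, 97.8% for KC-N, 99.2% for Ly6CHi-RM and 95.6% for Ly6CLo-RM. A region missing from the KN-RM list is therefore weaker evidence of closed chromatin than a region missing from another list. With 1 list per group there was no replicate error between lists, so no comparison below has a test or a p-value, and intervals cover counting error only.

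The question of how the 6 populations relate was addressed by the share of peaks that pairs of lists had in common. With every list reduced to its 34293 best-scored peaks, Ly6C-high blood monocytes and Ly6CHi-RM shared 84.4% of peaks, the highest value of the 15 pairs. KC-N and KN-RM shared 83.6%, Ly6CHi-RM and Ly6CLo-RM 82.2%, KC-H and KC-N 81.4%, and KC-H and KN-RM 78.9%. KN-RM shared less with the CD11b-high populations, whose titles have the same RM suffix, at 73.4% with Ly6CHi-RM and 73.0% with Ly6CLo-RM. It shared 67.9% with blood monocytes. KC-H and blood monocytes shared the least, at 66.7%. For the lists as deposited, random circular shifts left a mean of 0.536% to 0.997% of the peaks of one list of a pair overlapping the other. Of 100354 merged regions, 25441 (25.4%) were in all 6 lists and 27745 were in 1 list. All 3 F4/80-high lists and no other held 1896 regions, and the blood list and both CD11b-high lists and no other held 5742.

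**Figure D1:**
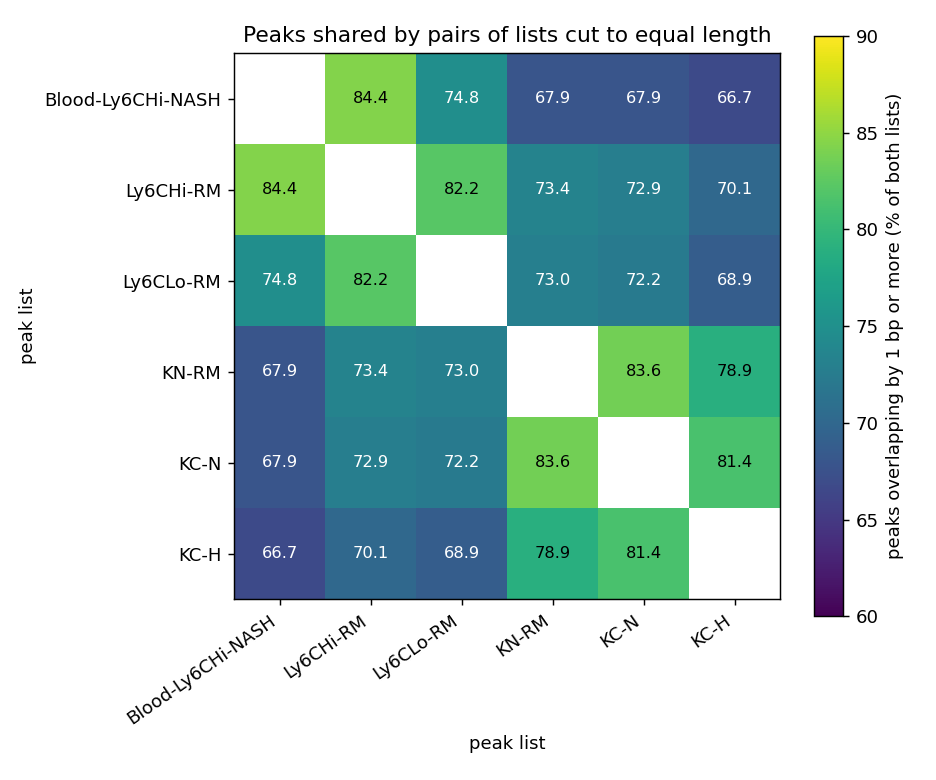
Each cell gives the percentage of peaks of the pair of lists that overlap a peak of the other by 1 bp or more, after every list was reduced to its 34293 best-scored peaks; both axes name the peak lists. Blood-Ly6CHi-NASH with Ly6CHi-RM (84.4%) and KC-N with KN-RM (83.6%) have the highest values, and Blood-Ly6CHi-NASH with KC-H has the lowest (66.7%).

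Differences between lists were taken from list-specific regions: peaks in the best-scored 50% of one list that no peak of the whole other list overlapped by 1 bp. Many such regions had a peak of the other list just beside them. Of the 36 highest-scoring list-specific regions, 3 per direction of each comparison, 35 had a peak centre of the other list 202 to 402 bp away. Some peaks led in more than 1 comparison and are counted each time, so these are not 36 separate peaks. Counts are therefore also given for list-specific regions with no peak centre of the other list within 1000 bp, a distance chosen after the data were seen.

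**Figure D2:**
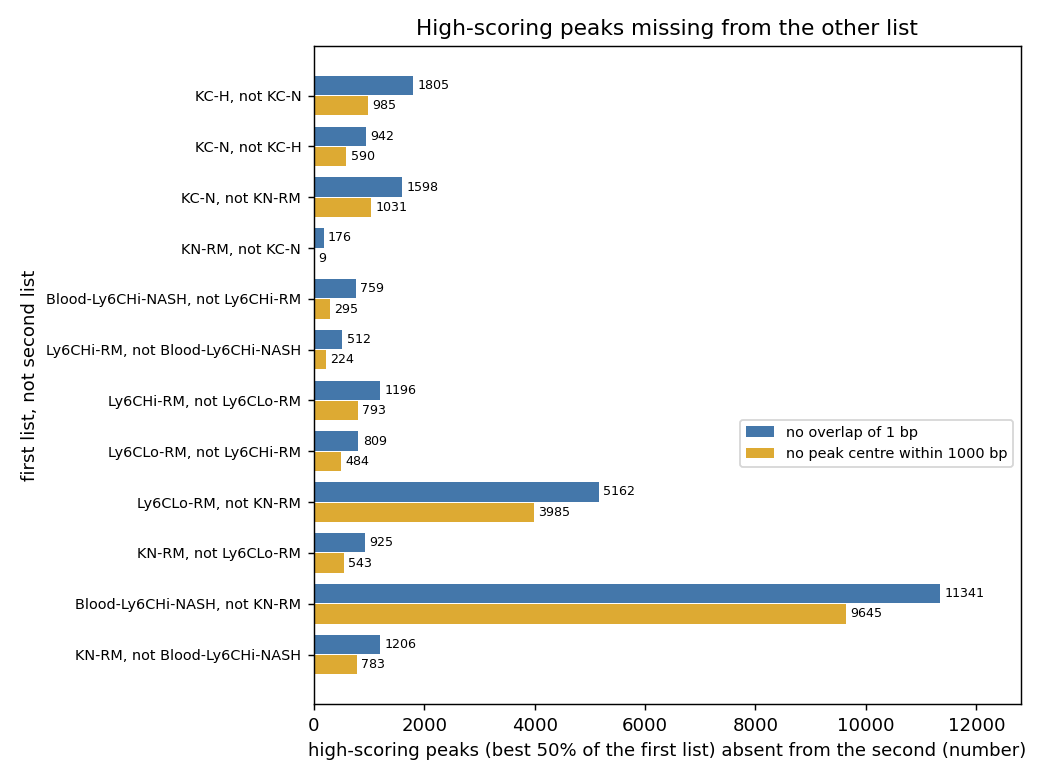
Bars give the number of peaks in the best-scored 50% of the first-named list that are absent from the second-named list, with absence taken as no overlap of 1 bp (blue) or as no peak centre within 1000 bp (yellow). The count for KN-RM without KC-N is 176 by overlap and 9 by distance, and the count for Blood-Ly6CHi-NASH without KN-RM is 11341 and 9645.

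The effect of the NASH diet on Tim4-positive Kupffer cells was examined by comparing KC-H with KC-N. Genes of Kupffer cell identity had list-specific regions of the control diet alone: 17 of KC-H at 11 of the 20 genes and 0 of KC-N, a balance below that of all 10000 random lists matched on peaks per gene. With equal-length lists there were 7 regions of KC-H at 5 genes and 0 of KC-N, again below all random lists. The middle 95% of such lists is called the matched range below. Timd4, which encodes the receptor Tim4 used in the sort (chromosome 11, 46810786 to 46844333 in mm10), had 17 peaks in KC-H and 1 in KC-N. The KC-N peak, at 46810556 to 46810756, overlapped a KC-H peak with a score of 95 but was outside the best-scored 50% of its list. Timd4 peaks thus give little support to the label of KC-N as Tim4-positive, on which every comparison with KC-N rests. Peaks do not measure the Tim4 protein used in the sort, so they do not contradict the label either. Clec4f, which encodes a Kupffer cell lectin (chromosome 6, 83644542 to 83656116), had 18 and 7 peaks, Cd5l had 24 and 13, and Marco, a scavenger receptor gene, had 15 and 7. Genes of lipid-associated macrophages of the Trem2 type lay in the opposite direction, with 13 list-specific regions of KC-N against 4 of KC-H, more in KC-N at 8 of 18 genes and more in KC-H at 1, above the matched range. Among them, the stress-response gene Atf3 had 5 regions of KC-N and 2 of KC-H, Cd9 had 21 peaks in KC-N and 13 in KC-H, and the lipid droplet gene Plin2 had 15 and 12. At Trem2 itself the lists held 4 peaks in KC-N and 3 in KC-H.

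The list of complement and dead cell uptake genes had 11 list-specific regions of KC-H and 1 of KC-N (percentile 0.23). Its members included Timd4 with 5 of the KC-H regions and Mertk, an uptake receptor gene, with 2 regions and with 29 peaks in KC-H against 14 in KC-N. Without Timd4, the member with the most regions, the balance would be within the random range of 7 more in KC-H to 4 more in KC-N. That range is for whole random lists, which kept their own leading genes, so the comparison leans toward the range. With equal-length lists the percentile was 14.6, inside the matched range. The list stayed below the range under the other 5 alternatives, at percentiles of 0.05 to 0.36. AP-1, EGR and early response genes had 14 regions of KC-N and 7 of KC-H (percentile 99.2), with 3 against 0 at Klf6 and 1 of KC-H at Fos. Atf3, which is in this list and in the Trem2-type list, had the most. Without it the balance of 4 more in KC-N would be within the random range of 9 more in KC-H to 5 more in KC-N. That range is again for whole random lists, so the same lean holds. The early response list lay inside the range at percentile 91.6 with a 20 kb window, 89.9 with all peaks and 94.3 with equal-length lists. Of the lists of other cell types, T and NK cell genes had 3 regions of KC-N, 2 at Klrb1c and 1 at Il7r, and 0 of KC-H (percentile 99.5, and 95.9 with all peaks). Lists of dendritic cell, neutrophil, B cell, hepatocyte, liver endothelial and stellate cell genes were inside the matched range. With all peaks, however, the hepatocyte list was above it (98.7, 6 of KC-N and 2 of KC-H). The housekeeping control, at 29.8 with list-specific regions, was then below it (1.80, 37 of KC-H and 4 of KC-N), the direction of the identity genes. LXR and lipid handling targets were inside the matched range (percentile 14.5), with 2 regions of KC-H each at Mertk and Apoe.

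Genes with the most list-specific regions of KC-H were Ldoc1 with 6, Pde10a with 5 and Timd4 with 5; Ldoc1 had 10 peaks in KC-H and 0 in KC-N. Those of KC-N were Xylt1 with 7, and Zfp469, Atf3 and Atp10a with 5 each; Xylt1, a xylosyltransferase gene, had 13 peaks in KC-N and 1 in KC-H. Cebpb, which encodes a transcription factor of myeloid cells, had 4 regions of KC-N and 0 of KC-H. In all, 1805 of 31750 high-scoring KC-H peaks were absent from KC-N (5.69%, 5.44% to 5.95%) and 942 of 25275 high-scoring KC-N peaks were absent from KC-H (3.73%, 3.50% to 3.97%). Without regions that had a centre of the other list within 1000 bp, 985 and 590 were left. With equal-length lists the order turned, with 445 of KC-H and 715 of KC-N. The highest-scoring regions of KC-H were near the ends of Zbtb20, Lcorl and Gsk3b, each with a KC-N centre 224 to 401 bp away. Those of KC-N were at Xpo1 and Napa, with KC-H centres 244 and 239 bp away, and at chromosome 1, 24613017 to 24613217, which was 25.2 kb outside Col19a1 and 20826 bp from the nearest KC-H centre. The chromosome 1 region had a tag count of 7454.5, against a list median of 26.9. Peaks in repeated or hard-to-map sequence were not filtered, so whether it is open chromatin was not tested.

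Regions of KC-N absent from KC-H were found in KN-RM at 69.2% (66.2% to 72.1%), in Ly6CHi-RM at 64.4%, in Ly6CLo-RM at 63.2% and in blood monocytes at 58.0%. Peaks of KC-N that KC-H shared, matched on score, were found in those 4 lists at 85.4% to 89.9%. Regions of KC-H absent from KC-N were found in KN-RM at 20.4% (18.6% to 22.3%), in blood monocytes at 45.8%, in Ly6CHi-RM at 41.2% and in Ly6CLo-RM at 35.7%, against 70.9% to 80.8% for matched shared peaks.

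**Figure D3:**
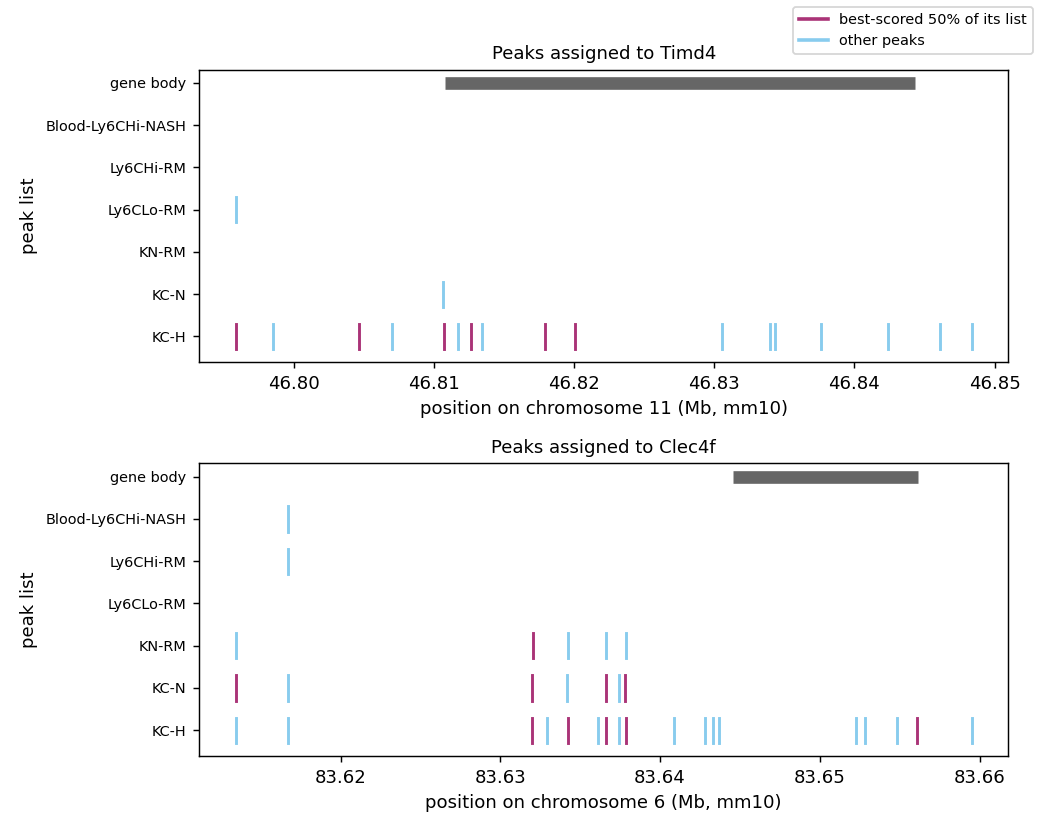
Vertical lines mark the centres of peaks assigned to Timd4 (top) and Clec4f (bottom) in each of the 6 lists, against chromosome position in Mb (mm10); the grey bar is the gene body, and dark lines are peaks in the best-scored 50% of their list. Timd4 has 17 peaks in KC-H, 1 in KC-N, 1 in Ly6CLo-RM and 0 in KN-RM, and Clec4f has 18 in KC-H, 7 in KC-N and 5 in KN-RM.

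Kupffer cells of the NASH diet labelled Tim4-positive and Tim4-negative were compared through KC-N and KN-RM. Marco had 7 peaks in KC-N and 0 in KN-RM, with 2 list-specific regions of KC-N. Id1, which encodes an inhibitor of DNA binding, had 3 regions of KC-N and 0 of KN-RM. Clec4f had 7 peaks in KC-N and 5 in KN-RM, Cd5l had 13 and 10, and Timd4, the gene of the marker that defines the 2 labels, had 1 and 0. The Kupffer cell identity genes as a group had 8 regions of KC-N and 1 of KN-RM, inside the matched range (percentile 3.64). With all peaks they had 56 and 3 and were below it (0.23), and with equal-length lists they had 0 and 1 (83.8). Slc7a2, a transporter gene, had 4 regions of KC-N and 0 of KN-RM, with 6 and 0 peaks, and Camk2d, Etv1, Myo10 and Trps1 also had 4 and 0.

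In the other direction the regions were few. Sfi1 had 4 regions of KN-RM, and Tnfaip3, an inhibitor of NF-kB signalling, and Sirpa had 2 each; none of these regions lay over 1000 bp from a KC-N centre. NF-kB inflammatory genes had 4 regions of each list and lay above the matched range (percentile 98.0), as did the housekeeping list, a control (98.5). By distance NF-kB genes lay inside it, at percentile 87.6, and also at 96.0 and 93.7 with windows of 20 and 1000 kb and at 97.4 by nearest gene end. The housekeeping list was inside the range by distance and with equal-length lists (88.6) and outside it under the other 4 alternatives. High-scoring peaks of KC-N absent from KN-RM numbered 1598 of 25275 (6.32%, 6.03% to 6.63%), and those of KN-RM absent from KC-N numbered 176 of 17146 (1.03%, 0.886% to 1.19%). By distance, 1031 and 9 were left, and with equal-length lists 283 and 294. The single regions of highest score were at Xpo1, Brpf1 and chromosome 2, 98666498 to 98666698, for KC-N. For KN-RM they were on an unplaced sequence and at chromosome 17, 39844461 to 39844661, and chromosome 2, 98666746 to 98666946, over 100 kb from any protein-coding gene. The chromosome 2 peaks had centres 248 bp apart and tag counts of 2387.9 in KC-N and 1434.8 in KN-RM. The list medians were 26.9 and 19.6. Repeated sequence was not filtered, so whether these regions are open chromatin was not tested. Of the KC-N regions absent from KN-RM, 81.9% (79.9% to 83.7%) were in KC-H and 57.9% in Ly6CLo-RM, against 94.9% and 85.5% of shared peaks matched on score.

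The step from the blood to the liver was examined by comparing Ly6C-high blood monocytes with Ly6CHi-RM. Early response genes had 9 list-specific regions of Ly6CHi-RM and 4 of the blood list (percentile 98.9), more in Ly6CHi-RM at 4 of 17 genes and more in blood at 1. Atf3 had 29 peaks in Ly6CHi-RM and 15 in blood, Dusp1 had 26 and 15, and Fosb had 19 and 10. Genes of the TGF-beta, BMP and Notch response had 5 regions of Ly6CHi-RM, of which 3 were at Rbpj, the transcriptional effector of Notch, and 0 of blood (percentile 99.1). The hypoxia-inducible lipid droplet gene Hilpda had 3 regions of Ly6CHi-RM and 0 of blood, with 5 and 1 peaks. Trem2-type genes had 4 regions of Ly6CHi-RM and 1 of blood, inside the matched range (percentile 97.4). They were above it by distance (99.2), with equal-length lists (7 against 0) and with all peaks (37 against 15). They stayed inside it with windows of 20 kb (2 against 1, percentile 82.0) and 1000 kb (97.2) and by nearest gene end (97.1). Gpnmb had 8 peaks in Ly6CHi-RM and 6 in blood, Cd9 had 16 and 14, and Spp1 had 5 and 7.

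The housekeeping list, a control, also lay above the matched range, with a percentile higher than those of the early response and TGF-beta lists, which limits what these show. It was inside the range with equal-length lists alone (77.9). With those lists early response genes had 14 regions of Ly6CHi-RM and 1 of blood, above all matched random lists. Antigen presentation genes (7 and 0) and fibrosis-linked factors (6 and 0) were also above the range. Complement and dead cell uptake genes (0 and 2) were below it. The hepatocyte list stood below the range (percentile 0.17), with 3 regions of blood at Alb, the albumin gene, and 0 of Ly6CHi-RM; Alb had 11 peaks in blood and 0 in Ly6CHi-RM. With equal-length lists the hepatocyte list was at percentile 50.2 and the TGF-beta list at 77.8, both inside the range. The TGF-beta list was also inside it with all peaks (67.6), by distance (93.0) and with a 20 kb window (96.4), and early response genes were inside it with windows of 20 and 1000 kb (93.0 with the wider). Per the labels, hepatic macrophages were obtained by perfusion and digestion of the liver with flavopiridol present. Blood monocytes did not come from digested liver, so tissue and isolation cannot be told apart in this comparison.

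In all, 759 of 34808 high-scoring blood peaks were absent from Ly6CHi-RM (2.18%, 2.03% to 2.34%), and 512 of 30746 of Ly6CHi-RM were absent from blood (1.67%, 1.53% to 1.81%). By distance 295 and 224 were left, and with equal-length lists the order turned to 281 and 369. Zbtb20 led the blood list with 5 regions, of which 1 was left by distance, and Zbtb16 had 3 with all 3 left. The highest-scoring blood regions were at the ends of Dnpep, Zbtb20 and Ripk2, and those of Ly6CHi-RM at Sertad2, Pgap2 and Ube2d3. Of the Ly6CHi-RM regions absent from blood, 85.4% (82.0% to 88.2%) were in Ly6CLo-RM, 68.0% in KC-N, 57.6% in KN-RM and 53.5% in KC-H, where matched shared peaks had 92.6%, 79.2%, 61.1% and 81.2%. Of the blood regions absent from Ly6CHi-RM, 26.7% (23.7% to 30.0%) were in Ly6CLo-RM, against 84.3% of shared peaks matched on score. The shares were 40.2% in KC-H, 33.9% in KC-N and 25.6% in KN-RM, against 76.5%, 69.4% and 51.8%.

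Ly6CHi-RM and Ly6CLo-RM were compared to see how recruited macrophages with high and low Ly6C differ. Antigen presentation genes had 8 list-specific regions of Ly6CLo-RM at 5 of 13 genes and 0 of Ly6CHi-RM (percentile 99.5). The MHC class II gene H2-Ab1 had 15 peaks in Ly6CLo-RM and 4 in Ly6CHi-RM, H2-Aa had 17 and 5, and Cd74, the invariant chain gene, had 19 and 12. Dendritic cell genes had 6 regions of Ly6CLo-RM and 0 of Ly6CHi-RM (percentile 99.6), with 2 at Ccr7, 2 at Tcf4 and 1 at Zbtb46. Early response genes had 11 and 3 regions (percentile 97.8), with 2 of Ly6CLo-RM and 0 of Ly6CHi-RM at Fosb. In the other direction, Runx1, a haematopoietic transcription factor gene, had 4 regions of Ly6CHi-RM and 0 of Ly6CLo-RM, with 41 and 25 peaks, and the fibronectin gene Fn1 had 2 and 0.

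By distance, antigen presentation genes were inside the matched range at percentile 81.7 and early response genes at 57.9. Early response genes were also inside it with a 20 kb window (97.4) and equal-length lists (95.6), and dendritic cell genes with all peaks (97.4) and equal-length lists (82.2). The monocyte receptor genes Ccr2 and Cx3cr1 had 6 and 9 peaks in Ly6CHi-RM and 2 and 6 in Ly6CLo-RM, and Cd9 had 16 and 19. Tcof1, which lies beside Cd74 on chromosome 18 (60813738 to 60848983, with Cd74 ending at 60812652), had the most regions of Ly6CLo-RM, 10. Mical3 followed with 6, and Etv6 and Ror1 with 5 each. High-scoring peaks of Ly6CHi-RM absent from Ly6CLo-RM numbered 1196 of 30746 (3.89%, 3.68% to 4.11%), and those of Ly6CLo-RM absent from Ly6CHi-RM 809 of 27310 (2.96%, 2.77% to 3.17%). By distance 793 and 484 were left, and with equal-length lists the order turned to 404 and 552. The highest-scoring regions were at Zbtb20, Phf19 and chromosome 17, 39844797 to 39844997, in Ly6CHi-RM, and at Zbtb20, Brpf1 and Cic in Ly6CLo-RM. Of the Ly6CHi-RM regions absent from Ly6CLo-RM, 93.7% were in blood monocytes, below the 97.0% of matched shared peaks. Of the Ly6CLo-RM regions absent from Ly6CHi-RM, 22.1% (19.4% to 25.1%) were in blood, 37.0% in KC-N and 23.1% in KN-RM, and matched shared peaks had 93.2%, 84.3% and 69.7%.

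Ly6CLo-RM and KN-RM, a CD11b-high and an F4/80-high population of the same diet, were compared next. Kupffer cell identity genes had 8 list-specific regions of KN-RM and 2 of Ly6CLo-RM (percentile 99.99), more in KN-RM at 6 of 20 genes and more in Ly6CLo-RM at 1. Cd5l had 10 peaks in KN-RM and 1 in Ly6CLo-RM, and Clec4f had 5 and 0. LXR and lipid handling targets had 14 regions of KN-RM and 4 of Ly6CLo-RM, above all matched random lists: the cholesterol exporter gene Abca1 had 5 and 0, and Mertk and the desaturase gene Scd1 had 2 and 0 each. Complement and dead cell uptake genes had 9 and 0, with Abca1 and Mertk in both lists, and fibrosis-linked secreted factors had 7 and 3, with 2 of KN-RM and 0 of Ly6CLo-RM at Igf1. Nr1h3, which encodes LXR alpha, had 2 peaks in each list. These 4 lists stayed above the matched range under all 6 alternatives tried for gene lists.

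Toward Ly6CLo-RM, dendritic cell genes had 13 regions and 0 of KN-RM (percentile 1.98), with 3 each at Flt3, Zbtb46, Tcf4 and Ccr7; the percentile was 2.57 with a 1000 kb window and 2.56 by nearest gene end, just inside the range. The forkhead gene Foxp1 had 14 regions of Ly6CLo-RM and 0 of KN-RM, Bach2 had 12 and 2, Tcof1 had 12 and 0, and Fosb had 10 and 0. Sfi1 had the most regions of KN-RM, 19, of which 5 were left by distance. In all, 5162 of 27310 high-scoring peaks of Ly6CLo-RM were absent from KN-RM (18.9%, 18.4% to 19.4%), and 925 of 17146 of KN-RM were absent from Ly6CLo-RM (5.39%, 5.07% to 5.74%). By distance 3985 and 543 were left, and with equal-length lists the order turned to 1371 and 1603. The highest-scoring regions were at Zbtb20, Etfdh and Wipi1 in Ly6CLo-RM. In KN-RM they were at Zbtb20, chromosome 17, 39843615 to 39843815, and on an unplaced sequence. KN-RM regions absent from Ly6CLo-RM were found in KC-N at 90.8% (88.8% to 92.5%) and in KC-H at 88%, but in Ly6CHi-RM at 36.3% and in blood at 36.0%. Matched shared peaks were found in these 4 lists at 94.8% to 99.3%.

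Last, Ly6C-high blood monocytes were compared with Tim4-negative Kupffer cells, KN-RM. Abca1 had 6 list-specific regions of KN-RM and 0 of blood, Itga9 had 8 and 0, Hilpda had 6 and 0, and Tnfaip3 had 5 and 0. LXR and lipid handling targets had 18 regions of KN-RM and 12 of blood, where the median of matched random lists was 24 more in blood than in KN-RM, and complement and uptake genes had 14 and 8. Antigen presentation genes had 9 and 3, with 3 and 0 each at Cd74 and H2-Eb1. Kupffer cell identity genes had 8 and 8, with 10 and 5 peaks at Cd5l; NF-kB inflammatory genes had 11 and 11.

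Those 5 lists lay above the matched range, as did Trem2-type genes (7 and 13), early response genes (9 and 14), TGF-beta response genes (7 and 23), lysosome genes (4 and 13) and fibrosis-linked factors (6 and 6). With equal-length lists, early response genes were inside the range at 96.2, TGF-beta response genes at 74.6 and lysosome genes at 96.0. TGF-beta response genes were inside it under the other 5 alternatives too (73.3 to 97.2), and lysosome genes with all peaks and by nearest gene end (95.3). Hepatocyte genes had 10 regions of blood, 5 at Hnf4a and 3 at Alb, and 1 of KN-RM (percentile 2.12, but 7.17 with equal-length lists and 3.45 with all peaks). Toward blood, Foxp1 had 24 regions, Pde4d 22 and Ptpre 19, each with 0 of KN-RM, and Flt3 had 7 and 0. Gpnmb had 6 peaks in blood and 3 in KN-RM, Spp1 had 7 and 1, Ly6c2 had 4 and 3, and Ccr2 had 6 and 2. In all, 11341 of 34808 high-scoring blood peaks were absent from KN-RM (32.6%, 32.1% to 33.1%) and 1206 of 17146 KN-RM peaks were absent from blood (7.03%, 6.66% to 7.43%). With equal-length lists the order turned to 2149 and 2465. The highest-scoring regions were at Ubp1, Brpf1 and Dnpep in blood; in KN-RM they were at Sp1, chromosome 17, 39843615 to 39843815, and on an unplaced sequence. KN-RM regions absent from blood were found in KC-N at 93.6% (92.1% to 94.9%), in KC-H at 87.9%, in Ly6CLo-RM at 50.9% and in Ly6CHi-RM at 44.7%, against 97.0% to 99.2% for matched shared peaks.

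**Figure D4:**
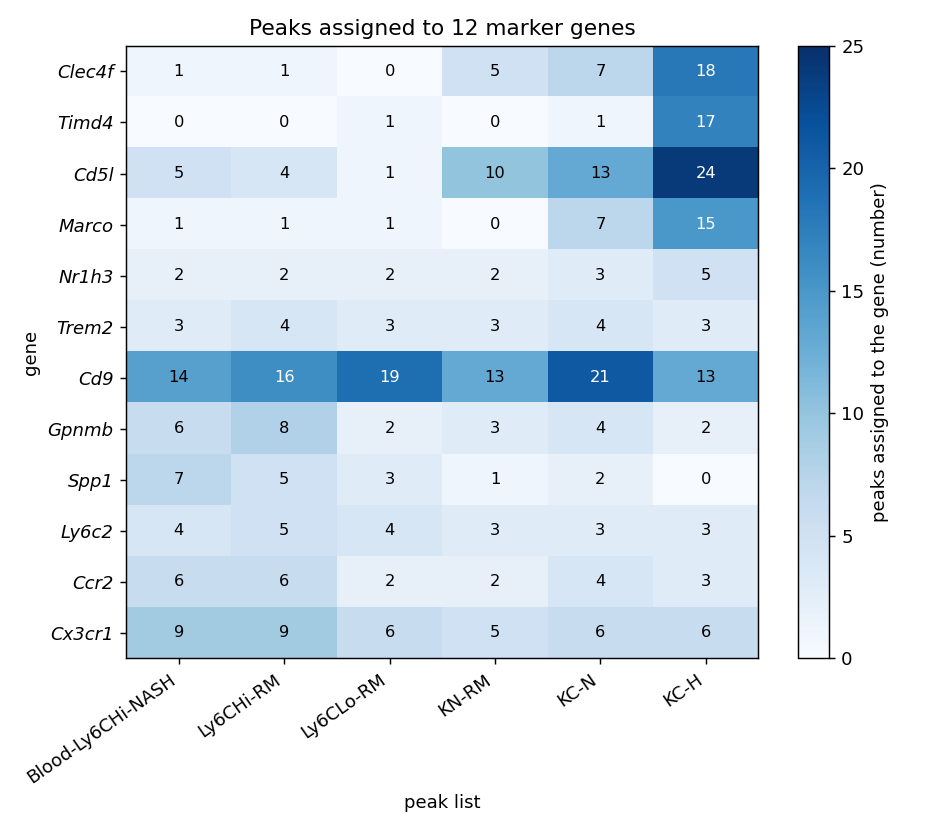
Cells give the number of peaks assigned to each of 12 marker genes (rows) in each peak list (columns), at any score. Timd4 has 17 peaks in KC-H and 1 or 0 in the other lists, Cd5l has 24 in KC-H, 13 in KC-N, 10 in KN-RM and 1 in Ly6CLo-RM, and Spp1 has 7 in Blood-Ly6CHi-NASH and 0 in KC-H.

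Across the 6 comparisons and 24 gene lists, 30 of 144 percentiles lay outside the matched range. By comparison, in the order given above, 5, 2, 4, 3, 5 and 11 lists were outside it. Independent lists of random genes would give 7.2 in all. That figure is not calibrated here, since comparisons share peak lists and some gene lists share genes. The housekeeping control was itself outside the range for KC-N against KN-RM (98.5) and blood against Ly6CHi-RM (99.985). The 144 percentiles describe the lists at hand and are not tests.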

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

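Peaks on sequences not placed on a chromosome entered no gene assignment and are listed here because they are signal outside the main measurement. There were 58 in the blood monocyte list, 134 in KC-H, 108 in KC-N, 134 in KN-RM, 58 in Ly6CHi-RM and 74 in Ly6CLo-RM. One of them led the KN-RM regions absent from Ly6CLo-RM and from blood by score, with a centre of the other list 335 and 269 bp away. No explanation was tested.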

How the results depend on the processing

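Rankings by tag count, nearest gene end and absence by distance were chosen after seeing the data; all other alternatives were chosen before. No paired analysis was possible because each group has 1 list made from both libraries, so no value per library exists; leaving out a replicate was not run for that reason, and motifs were not run because no genome sequence was used here. Depth per library is unknown, which limits what a missing peak shows. Results were counted as kept or moved by set limits whose values are not given here, so the counts of moved results depend on them. Centres within 200 bp kept all 15 overlaps and all 12 counts of list-specific regions within those limits. With nearly all peaks 200 bp wide, that rule is almost the same as an overlap of 1 bp, so little could move. Ranking by tag count kept the 12 counts. Autosomes and X kept the 6 list lengths, but they hold 99.6% to 99.9% of the peaks of a list, so this too was nearly fixed in advance. Gene end distances of 500 and 2500 bp moved all 6 gene end shares.

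Overlaps are in the order blood with KN-RM, blood with Ly6CHi-RM, KC-H with KC-N, KC-N with KN-RM, KN-RM with Ly6CLo-RM and Ly6CHi-RM with Ly6CLo-RM. As deposited they were 56.0%, 83.5%, 76.6%, 76.2%, 65.6% and 80.9%. They moved to 54.9%, 82.9%, 75.3%, 74.9%, 64.4% and 80.1% with 50% overlap, and to 67.9%, 84.4%, 81.4%, 83.6%, 73.0% and 82.2% with equal-length lists. With the better-scored 50% of every list they were 56.7%, 83.2%, 78.7%, 77.2%, 67.1% and 81.6%.

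Counts of list-specific regions are in the order KC-H without KC-N and the reverse, KC-N without KN-RM and the reverse, blood without Ly6CHi-RM and the reverse, Ly6CHi-RM without Ly6CLo-RM and the reverse, Ly6CLo-RM without KN-RM and the reverse, and blood without KN-RM and the reverse. With all peaks they were 19801, 6842, 18207, 1968, 14896, 6797, 14511, 7659, 25479, 5134, 40482 and 5187. With the best 25% they were 207, 165, 107, 57, 152, 81, 109, 107, 692, 196, 2226 and 300. Both follow from taking more or fewer peaks. With the better-scored 50% of every list, which shortens both lists, they were 750, 336, 859, 78, 430, 259, 508, 305, 2409, 390, 5580 and 550. Equal-length lists moved 9 of 12, to 445 for KC-H without KC-N, 283 and 294 for KC-N and KN-RM, 281 for blood without Ly6CHi-RM, 404 for Ly6CHi-RM without Ly6CLo-RM, 1371 and 1603 for Ly6CLo-RM and KN-RM, and 2149 and 2465 for blood and KN-RM. They also turned the order of all 6 comparisons (715 KC-N regions against 445 of KC-H). Longer lists lose their weaker peaks in this setting, but why the order turned was not tested. By distance, 10 of 12 moved: 985, 590, 1031, 9, 295, 224, 793, 484, 543 and 783, the last 2 being KN-RM without Ly6CLo-RM and without blood. With 50% overlap, KN-RM without KC-N moved to 413.

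The share of list-specific regions found in the list that held most of them moved with equal-length lists for 9 of 12 directions. It was 32.8% for KC-H without KC-N in blood, 87.6% for KC-N without KC-H in KN-RM, 68.6% for KC-N without KN-RM in KC-H and 48.3% for KN-RM without KC-N in blood. It was 91.1% for Ly6CHi-RM without blood in Ly6CLo-RM, 91.8% for Ly6CHi-RM without Ly6CLo-RM in blood, 44.4% for Ly6CLo-RM without Ly6CHi-RM in KC-N, 76.8% for Ly6CLo-RM without KN-RM in Ly6CHi-RM and 91.8% for blood without KN-RM in Ly6CHi-RM. By distance the shares were 35.4%, 77.6% and 87.6% for the first 3 of these, 29.2% for blood without Ly6CHi-RM in KC-H, 92.9%, 97.9% and 29.1% for the next 3, 96.5% for blood without KN-RM, and 98.5% in KC-N for KN-RM without Ly6CLo-RM and without blood. The cause was not tested. Regions in 1 list numbered 13427 with equal-length lists, which hold fewer peaks.

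The number of gene lists outside the matched range for KC-N against KN-RM was 1 with windows of 20 and 1000 kb, by nearest gene end and by distance, and 8 with all peaks. With all peaks it was 8 for blood against Ly6CHi-RM, 5 for Ly6CHi-RM against Ly6CLo-RM and 8 for Ly6CLo-RM against KN-RM. It was 1 by distance for Ly6CHi-RM against Ly6CLo-RM and 7 with equal-length lists for blood against KN-RM. The hepatocyte list of blood against Ly6CHi-RM, at percentile 0.17, passed to the other side of the middle at 50.2 with equal-length lists; the cause was not tested.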

Other observations

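Peak totals over whole gene lists, at any score, gave a view of the populations that the comparisons did not. The 16 classical monocyte genes held 110 peaks in blood monocytes, 101 in Ly6CHi-RM, 72 in Ly6CLo-RM, 76 in KC-H, 56 in KC-N and 43 in KN-RM. The 15 cholesterol synthesis genes held 58 peaks in blood and in Ly6CHi-RM, 50 in Ly6CLo-RM and 29 to 40 in the F4/80-high lists. The 11 dendritic cell genes held 85 peaks in blood, 69 in Ly6CHi-RM, 75 in Ly6CLo-RM, 78 in KC-H, 56 in KC-N and 34 in KN-RM. Of these genes, Flt3 and Kmo, chosen after their values were seen, had few peaks in F4/80-high cells: Flt3 had 12 in blood, 11 in each CD11b-high list and 1 in each F4/80-high list, and Kmo had 6, 6 and 4 and then 0 in all 3. Totals depend on list length, which was not corrected here. Regions held by all 5 NASH-diet lists and not by KC-H numbered 845, and 940 were in all 5 liver lists and not in blood.

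Sfi1 had 52 peaks in KC-H, 34 in KC-N and 43 in KN-RM, against 11 in blood, 19 in Ly6CHi-RM and 23 in Ly6CLo-RM. The KC-N region on chromosome 1, 25.2 kb outside Col19a1, had a normalized tag count of 7454.5, where the median peak of that list had 26.9. Peaks in repeated or hard-to-map sequence were not filtered here. Whether the signal at Sfi1, at this region and at the chromosome 2 and chromosome 17 regions named above reflects open chromatin was therefore not tested. Alb had 11 peaks in blood, 1 in KC-H, 1 in KC-N and 0 in the other 3 lists. KC-N, sorted as Tim4-positive per the labels, held 1 peak at Timd4, with a score of 26, at 46810556 to 46810756. Ly6CLo-RM held 1 with the same score at another position, 46795763 to 46795963, and KN-RM held 0. Whether the KC-N list and its samples are paired as labelled could not be checked here, and what is said of KC-N depends on it.

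Of the tests below, the one on regions open in every population was chosen after the result was seen, in place of an earlier one on the regions KC-H misses, 3.36% of those in all other 5 lists, which could not decide. With equal-length lists, KN-RM peaks overlapped KC-H and KC-N more than the CD11b-high recruited lists. As deposited, the lists of unequal length gave 76.2% with KC-N but 65.0% with KC-H, beside 65.6% with Ly6CLo-RM. Weighting of the lists toward promoters is argued against: over 1 kb from gene ends, the overlap of KN-RM with KC-N exceeded that with Ly6CLo-RM by 14.6 percentage points. That explanation needs no excess there. Low tag enrichment at peaks away from gene ends is not covered by this test. KN-RM and KC-N both had low mean tag counts, 27.2 and 38.5, against 83.4 in Ly6CLo-RM. Tim4-positive cells inside the Tim4-negative gate stay open, since KC-N had 0 high-scoring peaks at Timd4 to look for in KN-RM and 0 were found, so that test was void. That Tim4-negative cells may come to share open chromatin with resident Kupffer cells is a hypothesis; gate and mean tag count differ together between the lists.

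Regions that KC-N had and KC-H lacked were often found in the recruited lists, though less often than shared peaks of the same score. A KC-H list that misses regions open in every population stays open: of 677 such regions in a recruited list, blood and both recruited lists held 63.8% (60.1% to 67.3%), between the 50% and 90% set for the test, and 91.3% of shared high-scoring peaks. Recruited macrophages inside the KC-N gate could not be excluded: KC-N held 75% (61.8% to 84.8%) of 52 best-scored recruited regions absent from KC-H, between the bounds of 50% and 90% set beforehand, and KN-RM held 67.3%. Of the 34 with no KC-H centre within 1000 bp, KC-N had a centre within that distance at 30. This measure was chosen afterwards and is looser than overlap, so the bounds set for overlap do not apply to it. Mixing of cells and opening of the same regions in the resident cells of the NASH diet cannot be told apart here, and either may contribute.

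Regions near Kupffer cell identity genes were in KC-H and missing from KC-N. A shorter KC-N list as the whole cause is argued against: with equal-length lists the identity genes stayed at percentile 0 of matched random lists, though their KC-H regions numbered 7 at 5 genes in place of 17 at 11, so length may account for a part of the count. Sort purity and loss of regions within resident cells were not tested apart, and a part of the difference may come from KC-N cells of another origin. The loss as an effect of the diet is a hypothesis that 1 list per diet cannot test.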
